A study of Mus musculus with 19 samples.

How the data were processed

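The series holds 19 RNA-seq libraries of cells sorted by flow cytometry from mouse pancreatic ductal adenocarcinomas. The tumours grew after orthotopic transplantation of T-LOH KPC organoids, which are pancreatic tumour organoids, into C57BL/6J mice, and the mice received neratinib or vehicle for 2 weeks. Neratinib is an irreversible inhibitor of the ERBB family of receptor tyrosine kinases. PDPN+ cells, which the labels call cancer-associated fibroblasts (CAFs), gave 4 vehicle and 4 neratinib libraries. EpCAM+ cells, which the labels call epithelial cells, gave 6 vehicle and 5 neratinib libraries. The 5-digit number in each label was read as the animal, which is an inference: 11 numbers occur, 8 of them in both populations and 3 in EpCAM+ cells alone, and none in both treatments. On that reading each library of a group comes from a separate mouse, and the p-values rest on it. Below, V before the number marks a vehicle mouse and N a neratinib mouse.

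Per the labels' protocols, RNA was extracted with a column kit for small samples, and libraries were made with a low-input kit whose number of PCR cycles followed the amount of RNA. The labels do not give the cycle class of each library. Per the submitters' processing notes, Salmon 1.9.0 and the GRCm39/mm39 build were used. The transcriptome release and Salmon's options are not given in the sources used here. The deposited tables hold, per transcript, Salmon's estimated counts (not normalised), TPM (transcripts-per-million), and the effective length in bases, per the file headers. No strand setting is given, so reads of overlapping and antisense genes may not be separated, and near-identical copies such as the trypsin, elastase and haemoglobin genes may share reads.

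Each table lists 147828 transcripts, of which 137063 matched GENCODE M21 by identifier and were summed to 51707 genes, with the sums rounded to whole reads. That annotation belongs to GRCm38, another build than the submitters', so it was used only for gene names, GC content and length, and no coordinates are given. The 10765 unmatched transcripts held 4.07 to 8.96% of the reads of PDPN+ libraries and 1.77 to 2.26% of those of EpCAM+ libraries, and were tested apart as features of their own. All 500 entries of the gene lists were found, which are 491 distinct genes. Transcript reads per library ranged from 33.3 to 76.9 M (M stands for mega). Reads assigned to genes ranged from 30.3 to 48.1 M in PDPN+ libraries and from 39.4 to 75.4 M in EpCAM+ libraries. A count of 0 was read as up to 3 reads, which is at most 0.110 CPM (counts-per-million) in the shallowest library after scaling. Floors of this kind cover counting error only, since PCR copies without molecular identifiers are not independent molecules.

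Gene counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood F-test) at a Benjamini-Hochberg adjusted p under 0.05. Neratinib was compared with vehicle within each population alone. The interaction (the neratinib effect in PDPN+ cells minus that in EpCAM+ cells) and the contrast of the populations were fitted over all 19 libraries with 4 group means. CPM values are means over libraries with SD, scaled within the fit of their comparison. The 35 gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 where at least 3 members were tested, which compares a list with all other genes, and with adjustment over the lists of a comparison. The estimated correlation and fry, which asks whether the genes of a list move one way on balance and compares the list with no other genes, were alternatives. Genes were named by a rule: in each neratinib comparison up to 6 per direction among those passing with a mean of at least 4 CPM, or, where fewer than 3 passed, the 3 with the smallest unadjusted p; up to 3 members of each list, or 2 where none passed; and a fixed set (Pdpn, Epcam, Egfr, Erbb2, Erbb3, Areg, Hbegf, Nrg1, Dusp6, Spry4, Etv4, Etv5, Ccnd1, Mki67, Acta2, Il6, Cxcl1). For the interaction and the populations the rule took up to 4 per direction, and for the populations also up to 3 members of each list. Not every gene the rule names is printed. Library measures were compared between treatments by exact two-sided permutation tests. A list was counted as higher or lower in a neratinib library by comparing its mean log2 CPM with the average of the vehicle libraries. Single vehicle libraries can therefore lie beyond neratinib libraries so counted.

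Alternatives were DESeq2 1.42.0, its size factors in edgeR, no low-count filter, transcript-length offsets, limma voom with sample weights, log2(TPM + 1) with limma at a minimum TPM of 1, all 19 libraries in 1 fit, the column digit of a code in the deposited file names as a covariate, mouse as a block, and leaving out each library or mouse in turn. GC offsets, unmatched transcripts as features, and fits that mark or leave out libraries that stand apart were added after the data were seen. The mouse number was treated as pairing the populations because it was read as the animal. The deviations of the 2 libraries of a mouse from their group means, over 11091 genes, correlated at -0.181 to 0.0535 in the 8 mice. The highest correlation with an EpCAM+ library of another mouse of the treatment was larger in all 8, at 0.0275 to 0.146. That value is the highest of several, so it does not exclude the pairing, but expression lends the pairing no support.

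The procedures were tested on simulated counts drawn from the real means and library sizes and from the dispersions that edgeR estimated. In each of 4 simulations per comparison 200 genes were changed, 100 at each fold. No library was made to stand apart from its group, so shares of false calls may differ in the real data. For PDPN+ cells (a mean of 13509 genes tested by edgeR) edgeR recovered 0% of 2-fold and 1.50% of 4-fold changes. Of its calls 14.3% were false, at a mean of 0.25 false calls per simulation, so this share rests on few calls. For DESeq2 (13742 genes) 79.7% were false, at a mean of 112.8 false calls. For EpCAM+ cells (16717 genes) edgeR recovered 23.0% of 2-fold and 63.0% of 4-fold changes with 3.42% false, against 26.7% false for DESeq2 (17180 genes). For the interaction (19072 genes) edgeR recovered 0% and 4.75% with 9.52% false (a mean of 0.5 false calls), and DESeq2 (19538 genes) had 71.3% false. For the populations (19128 genes) edgeR recovered 6.75% and 29.5% with 6.45% false. A simulated 2-fold shift of the ERK list was called in 4 of 4 simulations in each population with the preset correlation, and with the estimated one in 4 of 4 for EpCAM+ and 2 of 4 for PDPN+ cells. Each gene was drawn independently, so these simulations hold no inter-gene correlation and do not show how the list test behaves with it. Smaller shifts of a list were not simulated.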

Results

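RNA of PDPN+ cells (CAFs) and EpCAM+ cells (epithelial cells) sorted from orthotopic pancreatic tumours was sequenced after 2 weeks of neratinib or vehicle. There were 4 vehicle and 4 neratinib PDPN+ libraries, and 6 vehicle and 5 neratinib EpCAM+ libraries, from 11 mice. Libraries held 30.3 to 75.4 M reads assigned to genes. Between 11876 and 18552 genes had at least 10 reads in PDPN+ libraries, and between 16485 and 17920 in EpCAM+ libraries. Mitochondrial genes took 6.14 to 19.5% of the reads of PDPN+ libraries and 2.15 to 2.89% of those of EpCAM+ libraries.

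To examine whether the sort separated the populations, PDPN+ libraries were compared with EpCAM+ libraries. Pdpn (ENSMUSG00000028583), which encodes podoplanin, stood at 540 ± 145 CPM in PDPN+ vehicle and 402 ± 35.1 in PDPN+ neratinib libraries (SD, n = 4 each), against 1.70 ± 0.844 (n = 6) and 1.42 ± 0.896 (n = 5) in the EpCAM+ groups, a log2 difference of 8.23 (SE 0.36). Epcam (ENSMUSG00000045394), an epithelial adhesion molecule, stood at 444 ± 382 and 261 ± 205 CPM in EpCAM+ vehicle and neratinib libraries and at 0.284 ± 0.334 and 0.0800 ± 0.0928 in the PDPN+ groups, a log2 difference of -11.05 (SE 0.93). With edgeR's quasi-likelihood test 9673 of 19626 genes differed, 4761 higher and 4912 lower in PDPN+ cells. With mouse as a block over the 8 mice with both populations the count was 6792, of which 38.2% were higher in PDPN+ cells against 49.2% in the fit without it.

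**Figure D1:**
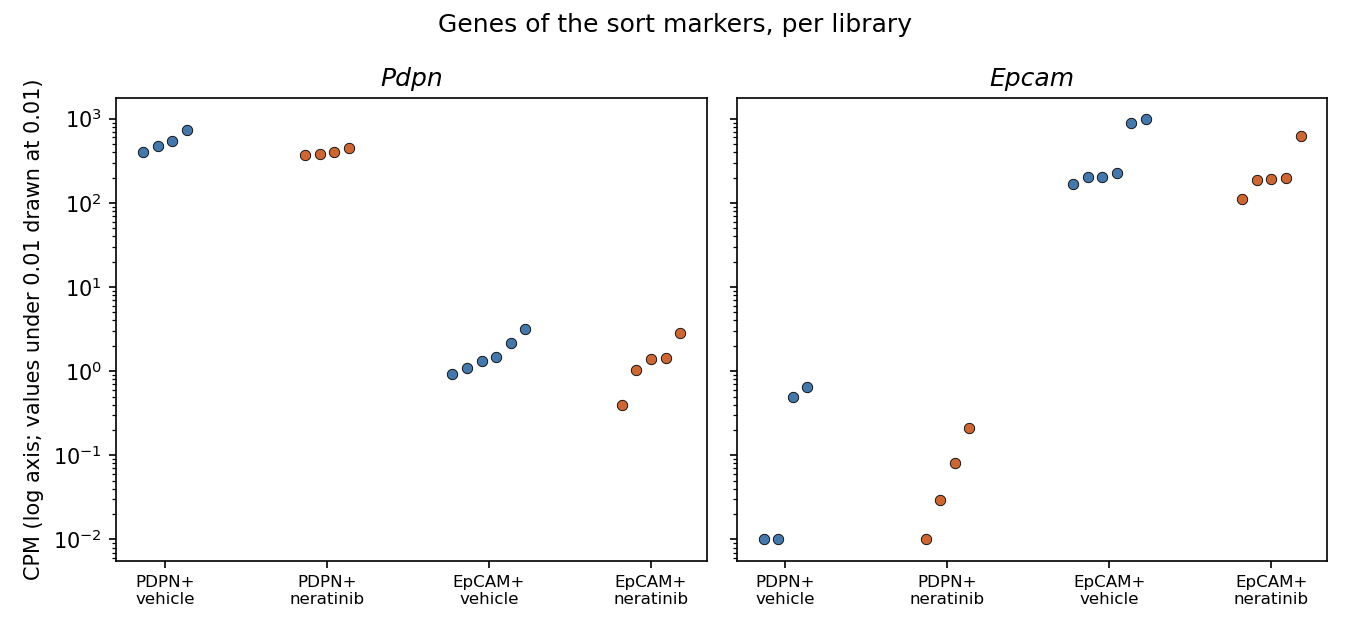
CPM of Pdpn and Epcam in each of the 19 libraries on a log axis, with 1 point per library ordered by value within its group; CPM were scaled over all libraries. Pdpn is high in the 8 PDPN+ libraries and Epcam in the 11 EpCAM+ libraries.

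Fibroblast and matrix genes were higher in PDPN+ cells without exception: 12 of 12 fibroblast identity genes and 21 of 21 matrix genes passed upward, among them Sparc (log2 difference 9.32), a collagen-binding glycoprotein, Bgn (9.18) and Vcan (7.86), both matrix proteoglycans. Of 19 myofibroblastic CAF genes 18 were higher and 1 lower, with Acta2, smooth muscle actin, at 7.67. Of 18 inflammatory CAF genes 15 were higher and 3 did not pass, and the chemokine gene Cxcl1 (8.46), the hyaluronan synthase gene Has1 (8.48) and the complement gene C3 (7.30) were among them. All 9 antigen-presenting CAF genes were higher, such as Cd74 (5.86) and H2-Ab1 (6.32), as were 7 of 8 mesothelial genes, such as Wt1 (9.02) and Upk3b (7.35), with 1 not passing. Higher members also made up 11 of 12 mesenchymal genes, 17 of 21 interferon, 8 of 9 MHC class I, 13 of 15 STAT3 and NF-kB, 12 of 16 TGF-beta (2 lower) and 11 of 17 other growth factor genes (3 lower), among these Igf1 at 8.79. Adjusted over the list alone, the same numbers of genes passed in each of these lists, except for 8 mesothelial, 19 myofibroblastic, 14 TGF-beta and 15 growth factor genes when both directions are counted.

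Epithelial genes were lower in PDPN+ cells in 17 of 17 cases, such as the mucin gene Muc1 (-8.40). Of 16 classical pancreatic cancer subtype genes 15 were lower and 1 higher, with the galectin gene Lgals4 at -6.77, and of 14 basal-like genes 10 were lower and 4 did not pass. The receptor and ligand genes of the ERBB family were lower in 6 of 10 cases, with 4 not passing. Hbegf, which encodes an EGFR ligand, was at -2.57. The receptor gene Egfr stood at 118 ± 92.4 and 128 ± 96.3 CPM in PDPN+ vehicle and neratinib libraries. In EpCAM+ libraries it stood at 73.5 ± 28.2 and 71.0 ± 14.9, each population scaled alone. Of 22 ERK output genes 9 were lower, such as Ccnd1, cyclin D1, at -4.41, and 5 higher. Cholesterol synthesis genes were lower in 16 of 20 cases (Sqle -2.32, Msmo1 -2.24), glycolysis and hypoxia genes in 10 of 18 (2 higher), and islet genes in 8 of 8. The kinase gene Ripk4, the sphingolipid synthesis gene Sptssb and the secreted channel regulator gene Clca1 had 0 reads in all 8 PDPN+ libraries, and their means in EpCAM+ libraries were at least 1874-fold, 1775-fold and 1354-fold higher, against a floor of 3 reads in the shallowest library. In the reverse direction Slc2a13 and Wif1 had 0 reads in all 11 EpCAM+ libraries and were at least 195-fold and 174-fold higher in PDPN+ cells on average, with some PDPN+ libraries also at 0. Adjusted over the list alone, 17 epithelial, 16 classical, 10 basal-like, 6 ERBB, 14 ERK, 16 cholesterol, 13 glycolysis and 8 islet genes passed.

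Members of the remaining lists, counted as higher, lower and not passing, split as follows. Proliferation genes gave 2, 2 and 23, unfolded protein and integrated stress response genes 3, 6 and 8, p53 targets 5, 2 and 8, and lysosome genes 7, 2 and 5. Dissociation stress genes gave 7, 1 and 8, acinar genes 1, 8 and 8, macrophage and monocyte genes 4, 1 and 8, and neutrophil genes 1, 1 and 7. Lymphocyte and dendritic cell genes each gave 1, 1 and 3, blood endothelial genes 6, 0 and 5, and lymphatic endothelial genes 3, 0 and 1. Pericyte and smooth muscle genes gave 5, 0 and 3, Schwann cell genes 1, 2 and 2, and red cell and platelet genes 1, 1 and 5. Adjusted over the list alone, as many genes of each of these lists passed in all, except for 4 macrophage and monocyte genes.

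To examine how neratinib changed CAFs, the 4 PDPN+ neratinib libraries were compared with the 4 PDPN+ vehicle libraries. No single gene passed, while 3 of 33 gene lists did: glycolysis and hypoxia genes and cholesterol synthesis genes were lower, and extracellular matrix genes were higher, with neratinib. With an estimated correlation 0 of 33 lists passed (smallest adjusted p = 0.676), and with fry 0. Crabp2 (ENSMUSG00000004885), which encodes a retinoic acid carrier, had the smallest unadjusted p: it stood at 75.5 ± 32.9 CPM with vehicle and 9.30 ± 3.56 with neratinib (SD, n = 4 each), a log2 fold change of -3.02 (SE 0.57), and all 4 neratinib libraries lay below every vehicle library. The same held for the pleckstrin-domain gene Plekhb1, at 20.8 ± 12.1 and 0.0430 ± 0.0656 CPM, and for D3Ertd751e, at 14.0 ± 8.86 and 0.0339 ± 0.0482. All were chosen by that p, so separated groups follow from the choice and lend no further support. The genes with the smallest p in the other direction were the collagen gene Col6a1 (log2 fold change 0.90), Zswim4 (1.86) and Fam161b (5.49).

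For PDPN+ cells edgeR called 0 of 14437 genes, with 331 at an unadjusted p under 0.05 (134 higher, 197 lower) where chance gives 721.9. The smallest adjusted p was 1.00. DESeq2 called 73 genes (23 higher, 50 lower), limma voom 0 and limma on log2(TPM + 1) 0, and edgeR with all 19 libraries in 1 fit called 111 (21 higher, 90 lower). DESeq2 gave adjusted p of 7.38e-06 for Crabp2, 1.24e-10 for Plekhb1, 5.41e-09 for D3Ertd751e, 0.00364 for Fam161b, 0.166 for Col6a1 and 0.248 for Zswim4. The fit of all 19 libraries gave 0.0635, 0.00104, 5.82e-04, 0.0257, 0.607 and 0.0674 in the same order, and over all alternatives the adjusted p of each ran up to 1. That fit shares 1 dispersion per gene with the EpCAM+ libraries, whose spread was smaller. Under it the genes at an unadjusted p under 0.05 went from 331 to 3165 in PDPN+ cells and from 524 to 204 in EpCAM+ cells. Its PDPN+ calls may therefore rest on SEs that are too small. The median SE of a log2 fold change was 1.06 in PDPN+ cells fitted alone, so most changes of 2-fold were not detectable at this spread. In simulated data, drawn from edgeR's own dispersions, 79.7% of the calls of DESeq2 were false. How many of its 73 calls in the real data are false was not tested. Of the 4 vehicle libraries 2, V53175 and V53188, had the fewest genes with at least 10 reads (12057 and 11876) and lay at 210 and 180 on the first principal component of the PDPN+ libraries, against -86.3 to -43.8 for the other 6. These 2 were also unlike each other. They lay at 199.7 and -221.3 on the second component, with 22.61% of the variance. The Pearson correlation of their log2 CPM, 0.67, was the lowest of the PDPN+ pairs within a group.

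Among glycolysis and hypoxia genes 16 of 18 had a negative log2 fold change in PDPN+ cells (median -0.51, camera adjusted p = 1.54e-04, and adjusted p = 0.676 with an estimated correlation). The mean log2 CPM of the list was below the vehicle average in 4 of 4 neratinib libraries. The groups overlapped, with V53175 (5.77) below N53184 (6.36) and N53194 (5.84). Pfkl, a phosphofructokinase gene, stood at 240 ± 97.2 CPM with vehicle and 113 ± 16.6 with neratinib, and the glucose transporter gene Slc2a1 at 142 ± 60.3 and 57.3 ± 36.0. Cholesterol synthesis genes were negative in 14 of 18 cases (median -0.69) and below the vehicle average in 4 of 4 neratinib libraries (adjusted p = 0.00175, and adjusted p = 0.676 with an estimated correlation). Here too V53175 (3.80) lay below N53180 (4.15), N53184 (3.91) and N53194 (4.37). Fdps, a farnesyl diphosphate synthase gene, had a log2 fold change of -0.98 and Sqle, a squalene epoxidase gene, of -1.25. Extracellular matrix genes were positive in 17 of 20 cases (median 0.36) and higher on average in 3 of 4 neratinib libraries (adjusted p = 0.00175, and adjusted p = 0.877 with an estimated correlation). Col3a1 stood at 4680 ± 1005 CPM with vehicle and 7751 ± 1445 with neratinib and Col6a1 at 621 ± 53.5 and 1158 ± 310. The 4 neratinib libraries lay above every vehicle library for both collagen genes, which were chosen for the smallest unadjusted p in their list. No member of the 3 lists passed over all genes or adjusted over the list alone. Without the neratinib library of mouse N53178 the cholesterol call (median -0.37, adjusted p = 0.0946) and the matrix call (0.109) ended, and without the vehicle library of mouse V53179 the matrix call ended (0.0518). Without V53185 the matrix median was 0.63.

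CAF subtype markers did not pass in PDPN+ cells. Acta2 stood at 169 ± 96.1 CPM with vehicle and 205 ± 144 with neratinib, Il6 at 145 ± 79.8 and 72.1 ± 16.2, Pdgfra, a receptor gene of inflammatory CAFs, at 925 ± 366 and 491 ± 71.8, and Cxcl1 at 618 ± 152 and 505 ± 119 (unadjusted edgeR p of 0.640, 0.0334, 0.0156 and 0.305). The median log2 fold change was 0.12 for myofibroblastic, -0.25 for inflammatory and -0.50 for antigen-presenting CAF genes. ERBB receptor and ligand genes had a median of -0.26 over 6 members and ERK output genes of 0.01 over 22, with Egfr at 0.12, Hbegf at -0.31, Dusp6 at 0.14 and Spry4 at -0.06. The other medians were -0.09 for TGF-beta, 0.09 for STAT3 and NF-kB, 0.11 for interferon, -0.08 for MHC class I, 0.52 for proliferation, -0.18 for unfolded protein and integrated stress response, 0.07 for lysosome and 0.20 for other growth factor genes. They were -0.09 for epithelial, 0.21 for classical, -0.20 for basal-like, 0.23 for mesenchymal, 0.20 for fibroblast, -0.01 for dissociation stress and 0.01 for mesothelial genes, and -0.00236 for p53 targets. Markers of other cells had medians of -0.23 (acinar), -0.14 (islet), 2.37 (macrophage and monocyte), 0.59 (neutrophil), 0.73 (blood endothelial), -0.49 (lymphatic endothelial), -0.50 (pericyte and smooth muscle), 0.47 (Schwann cell) and -0.85 (red cell and platelet). The adjusted p of these 30 lists ran from 0.348 to 0.987, none had a member passing over all genes or adjusted over the list alone, and the lymphocyte and dendritic cell lists had 2 tested members each and no list test. Median, mean and direction of the test differed in sign for the inflammatory CAF, ERK, STAT3 and NF-kB, MHC class I, p53, lysosome, classical, islet, neutrophil and lymphatic lists. Without V53188 the myofibroblastic list passed (median 0.47, adjusted p = 0.0318), as did the antigen-presenting list (-0.64, 0.00273), without N53184 the basal-like list (-1.20, 0.0302) and without V53179 the blood endothelial list (1.29, 0.0294). The mitochondrial share of reads was 10.5 ± 4.89% with vehicle and 15.6 ± 3.24% with neratinib (exact permutation p = 0.143, where 0.0286 is the smallest possible).

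**Figure D2:**
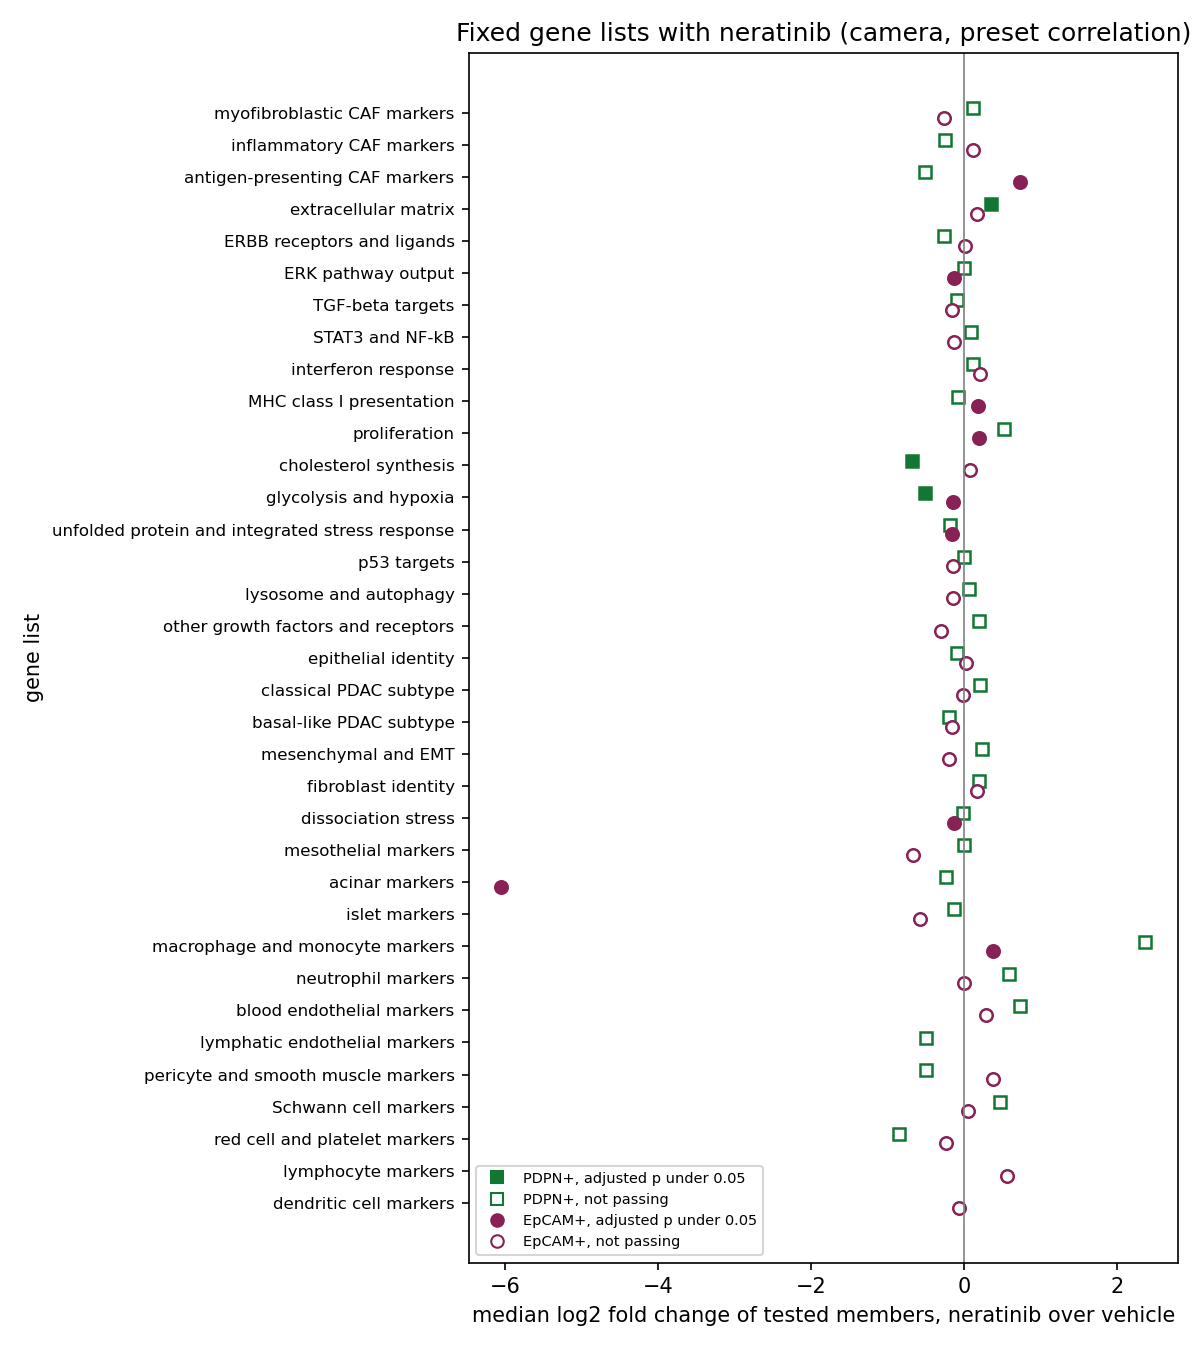
Median log2 fold change (neratinib over vehicle) of the tested members of each gene list in PDPN+ cells (squares) and EpCAM+ cells (circles); filled symbols passed camera with the preset correlation. The 3 filled squares are matrix genes on the higher side and cholesterol and glycolysis genes on the lower side, and the acinar genes of EpCAM+ cells have a median of -6.05.

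To examine how neratinib changed tumour epithelial cells, the 5 EpCAM+ neratinib libraries were compared with the 6 EpCAM+ vehicle libraries. No single gene passed, and 9 of 34 gene lists did. With an estimated correlation 0 of 34 lists passed (smallest adjusted p = 0.185), and with fry 0. Lgals3 (ENSMUSG00000050335), which encodes galectin-3, stood at 772 ± 78.6 CPM with vehicle (SD, n = 6) and 507 ± 45.7 with neratinib (n = 5), a log2 fold change of -0.61 (SE 0.10). Car2 (ENSMUSG00000027562), a carbonic anhydrase gene, stood at 1203 ± 190 and 2158 ± 361 CPM, a log2 fold change of 0.84 (SE 0.14). All 5 neratinib libraries lay outside the vehicle range for both genes. The genes named in this comparison were chosen for the smallest unadjusted p, so separated groups follow from the choice and lend no further support. Gadd45g, a stress-response gene, also lay below every vehicle library in 5 of 5 (104 ± 12.3 against 60.4 ± 15.2 CPM), Ugt1a6a, a glucuronosyltransferase gene, above it in 5 of 5 (40.6 ± 6.02 against 76.9 ± 22.0), and Ggh, a gamma-glutamyl hydrolase gene, below it in 4 of 5 (65.0 ± 9.54 against 40.6 ± 5.51).

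For EpCAM+ cells edgeR called 0 of 17200 genes, with 524 at an unadjusted p under 0.05 (260 higher, 264 lower) where chance gives 860, and the smallest adjusted p, that of Lgals3 and Car2, was 0.616. DESeq2 called 15 genes (4 higher, 11 lower), limma voom 0 and limma on log2(TPM + 1) 0. DESeq2 gave adjusted p of 4.39e-04 for Lgals3, 0.00293 for Car2, 0.0297 for Ggh, 0.0317 for Ugt1a6a and 0.0730 for Gadd45g, while the other alternatives ran up to 1 for each of them. On the first principal component, with 38.04% of the variance, the vehicle libraries of mice V53175 and V53176 and the neratinib library of mouse N53178 lay at -94.4 to -85.5 and the other 8 at 18.4 to 49.2. With these 3 libraries marked by a covariate edgeR called 0 genes, with 936 at an unadjusted p under 0.05, and without them 0 genes, with 797.

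**Figure D3:**
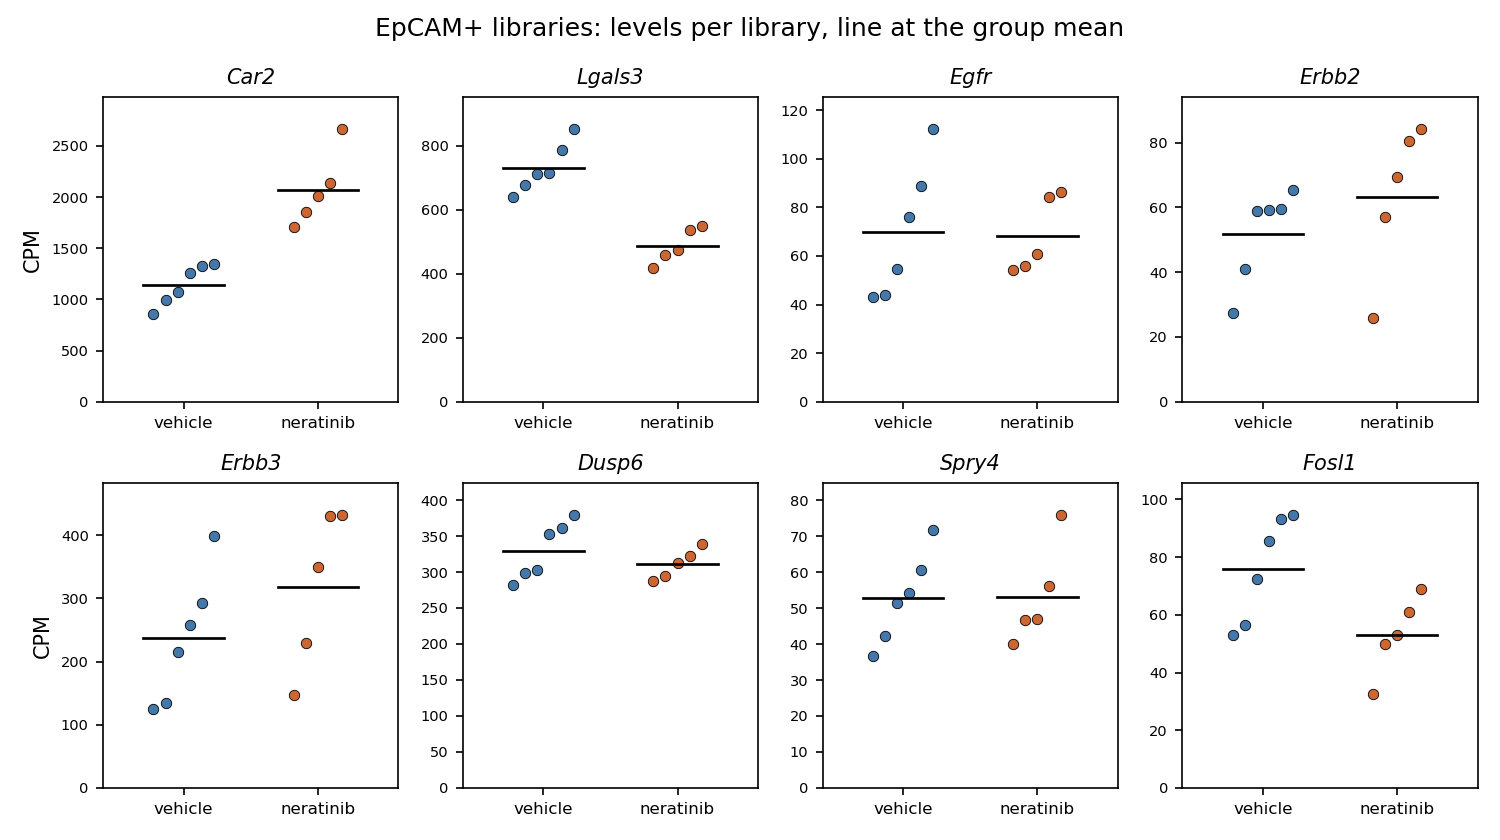
CPM of 8 genes in the 6 vehicle and 5 neratinib EpCAM+ libraries, with 1 point per library ordered by value within its group and a line at the group mean; CPM were scaled over all 19 libraries. The groups do not overlap for Car2 and Lgals3, which were chosen for their small unadjusted p. They overlap for the ERBB receptor genes and for Dusp6, Spry4 and Fosl1.

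No single ERBB receptor or ERK output gene passed in EpCAM+ cells, where edgeR recovered 23.0% of simulated 2-fold changes. Egfr stood at 73.5 ± 28.2 CPM with vehicle and 71.0 ± 14.9 with neratinib, Erbb2 at 54.8 ± 15.1 and 65.7 ± 23.8, and Erbb3 at 249 ± 104 and 329 ± 125. The 10 tested ERBB receptor and ligand genes had a median log2 fold change of 0.01, with 5 positive and 5 negative, and their list did not pass (camera adjusted p = 0.855, higher on average in 3 of 5 neratinib libraries). ERK output genes fell as a list: 19 of 22 were negative (median -0.14), and the mean was lower in 4 of 5 neratinib libraries (adjusted p = 0.0225, and adjusted p = 0.461 with an estimated correlation). The dissociation stress list, which shares Egr1 with the ERK list, had the same median (-0.14). Its mean log2 fold change was -0.33, against -0.19 for the ERK list. Fosl1, an AP-1 gene, stood at 80.1 ± 18.5 and 55.3 ± 13.7 CPM, Dusp6, an ERK phosphatase gene, at 347 ± 36.2 and 324 ± 25.3, and the feedback inhibitor gene Spry4 at 55.9 ± 13.3 and 55.3 ± 13.7. Log2 fold changes were -0.20 for Etv4, -0.12 for Etv5, 0.52 for Etv1, -0.15 for Ccnd1, -0.77 for Areg and -0.12 for Hbegf. Proliferation genes rose as a list, with 23 of 27 positive (median 0.20) and a mean above the vehicle average in 5 of 5 neratinib libraries (adjusted p = 0.00123, and adjusted p = 0.461 with an estimated correlation). The highest mean log2 CPM of the list was that of a vehicle library, V53192 (5.21). Top2a had a log2 fold change of 0.45, Cdc6 of 0.53 and Mki67 of 0.06. No ERBB, ERK or proliferation gene passed over all genes or adjusted over the list alone. The ERK call ended without each of 6 libraries, at adjusted p of 0.240 (N53178), 0.0588 (N53193), 0.0642 (V53179), 0.107 (V53185), 0.0572 (V53188) and 0.0846 (V53192). The ERK median was -0.23 without N53180, -0.24 without V53175 and -0.22 without V53176. The proliferation call ended without V53185 (0.0505, with a median of 0.13), and the median was 0.10 without N53193, 0.13 without V53176 and 0.31 without V53192.

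Antigen-presenting CAF genes, macrophage and monocyte genes and MHC class I genes rose as lists in EpCAM+ cells. Of 9 antigen-presenting CAF genes, most of which encode MHC class II molecules and partners that leukocytes also express, 8 were positive (median 0.74), with a higher mean in 5 of 5 neratinib libraries (adjusted p = 1.36e-04, and adjusted p = 0.372 with an estimated correlation). H2-Ab1 stood at 2.77 ± 2.66 and 7.07 ± 3.92 CPM and H2-Eb1 at 0.903 ± 0.647 and 2.39 ± 1.38. Macrophage and monocyte genes were positive in 8 of 13 cases (median 0.38) and higher on average in 4 of 5 neratinib libraries (adjusted p = 0.0128, and adjusted p = 0.461 with an estimated correlation). The complement genes C1qa and C1qb, expressed by macrophages, stood at 0.257 ± 0.0901 against 1.21 ± 1.14 and at 0.532 ± 0.395 against 2.56 ± 2.04 CPM. MHC class I genes were positive in 8 of 9 cases (median 0.18) and higher on average in 4 of 5 (adjusted p = 0.0285, and adjusted p = 0.461 with an estimated correlation), with Nlrc5 at 0.640 ± 0.590 and 2.89 ± 4.56 CPM and Psmb8 at 3.11 ± 1.72 and 5.77 ± 3.48. Of the abundant members, B2m had a log2 fold change of 0.13 and H2-K1 of 0.05. No member passed over all genes, and 0 antigen-presenting, 3 macrophage and 0 MHC class I genes passed adjusted over the list alone. The macrophage call ended without N53178 (adjusted p = 0.380, with a median of -0.12), V53179 (0.118, 0.22) or V53192 (0.0846), and its median was 0.16 without N53194 and 0.25 without V53185. The MHC class I call ended without N53178 (0.116, with a median of 0.08), N53184 (0.574, 0.04), V53179 (0.0965) or V53192 (0.152, 0.07), and its median was 0.36 without N53180, 0.28 without N53193 and 0.35 without V53175.

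Dissociation stress genes, unfolded protein and integrated stress response genes, and glycolysis and hypoxia genes fell as lists in EpCAM+ cells, by little. The first of these lists was negative in 14 of 16 cases (median -0.14), with Jund at -0.45 and Hspa1a at -0.76, and lower on average in 4 of 5 neratinib libraries (adjusted p = 0.00597, and adjusted p = 0.185 with an estimated correlation). Unfolded protein and integrated stress response genes were negative in 14 of 17 cases (median -0.16, with Ddit3 at -0.53 and Chac1 at -0.63) and below the vehicle average in 5 of 5 (adjusted p = 0.0153, and adjusted p = 0.372 with an estimated correlation). The lowest mean log2 CPM of the list was that of a vehicle library, V53175 (5.79). Glycolysis and hypoxia genes were negative in 14 of 18 cases (median -0.15; Pgk1 -0.28, Adm -0.72) and lower in 4 of 5 (adjusted p = 0.0128, and adjusted p = 0.461 with an estimated correlation). No member of these lists passed over all genes or adjusted over the list alone. Without N53178 the calls of all 3 lists ended (adjusted p of 0.0792, 0.0792 and 0.213 in the order given). The dissociation stress median was -0.21 without N53180, -0.27 without N53184 and -0.21 without V53188. The unfolded protein call also ended without N53194 (0.0528, with a median of -0.05), V53179 (0.0642), V53188 (0.0783) or V53192 (0.0846), and the glycolysis call without N53180 (0.0963), V53179 (0.141, with a median of -0.10) or V53188 (0.0568). Without N53193 the glycolysis median was -0.24.

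Acinar genes, which encode digestive enzymes of the exocrine pancreas, had the largest list difference. They were negative in 10 of 13 cases (median -6.05) and lower on average in 5 of 5 neratinib libraries (adjusted p = 8.95e-08, and adjusted p = 0.433 with an estimated correlation). No acinar gene passed over all genes and 10 passed adjusted over the list alone. The elastase gene Cela2a stood at 42.8 ± 66.3 CPM with vehicle and 0.213 ± 0.433 with neratinib. Vehicle libraries were far apart: the 13 genes summed to 1191 CPM in mouse V53192, 298 in V53188, 274 in V53185 and 122 in V53176, but to 12.0 in V53175 and 8.41 in V53179, against 8.79 to 40.4 in the neratinib libraries. The call ended without V53185 (adjusted p = 0.119), V53188 (0.0614) or V53192 (0.0871, with a median of -4.03).

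**Figure D4:**
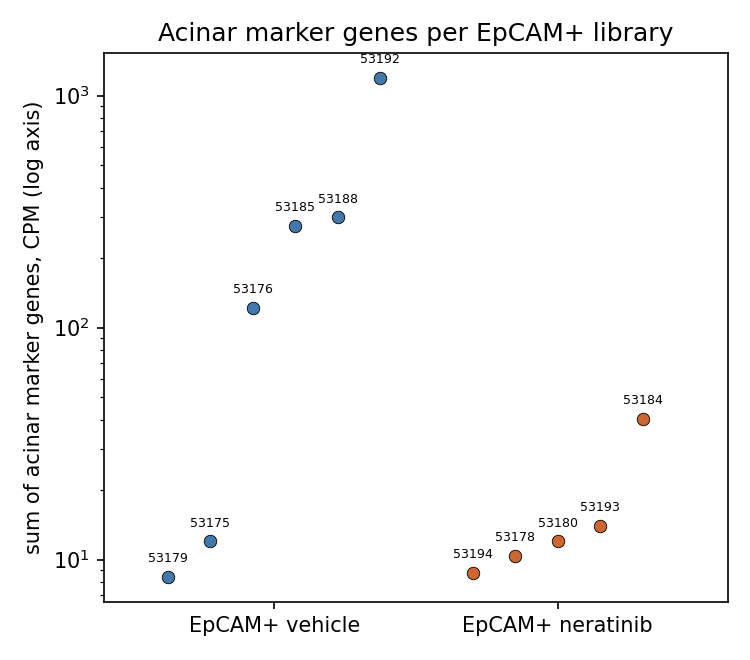
Sum of the CPM of 13 acinar genes in each EpCAM+ library on a log axis, with 1 point per library labelled by mouse. Of the 6 vehicle libraries 4 lie between 122 and 1191 CPM, and the 5 neratinib libraries and the other 2 vehicle libraries lie at 40.4 CPM or less.

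The other 25 lists tested in EpCAM+ cells did not pass, with adjusted p from 0.0610 (STAT3 and NF-kB, median -0.13) to 0.993 (classical subtype, -0.02). Medians were -0.26 for myofibroblastic and 0.12 for inflammatory CAF genes, 0.17 for matrix, -0.16 for TGF-beta, 0.21 for interferon, 0.07 for cholesterol synthesis, -0.15 for p53, -0.15 for lysosome and -0.31 for other growth factor genes. They were 0.03 for epithelial, -0.15 for basal-like, -0.19 for mesenchymal, 0.17 for fibroblast, -0.67 for mesothelial and -0.57 for islet genes. Other cell types had medians of -0.00152 (neutrophil), 0.57 (lymphocyte), -0.07 (dendritic cell), 0.29 (blood endothelial), 0.38 (pericyte and smooth muscle), 0.05 (Schwann cell) and -0.24 (red cell and platelet). No member of these lists passed over all genes or adjusted over the list alone. The lymphatic list had 1 tested member, Prox1 (log2 fold change -1.07, unadjusted p = 0.0452 by edgeR), and no list test. Median, mean and direction of the test differed in sign for the ERBB, lysosome, epithelial, classical and fibroblast lists.

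Leaving out 1 EpCAM+ library brought 11 of these lists past the threshold, given here with the median and adjusted p without it. STAT3 and NF-kB genes passed on the lower side without N53184 (-0.24, 0.0155), N53193 (-0.12, 0.0373), V53175 (-0.16, 0.0447) or V53176 (-0.20, 0.0395). Basal-like genes did so without N53184 (-0.15, 0.0458), N53194 (-0.38, 0.00914), V53175 (-0.23, 0.0124) or V53176 (-0.24, 0.0386), and other growth factor genes without N53194 (-0.27, 0.0262), V53175 (-0.21, 0.0128), V53176 (-0.20, 0.0276) or V53179 (-0.35, 0.0317). TGF-beta targets passed on that side without N53194 (-0.23, 0.0288) or V53175 (-0.19, 0.0212), myofibroblastic genes without V53175 (-0.24, 0.0166), fibroblast genes without N53194 (-0.78, 0.00349), mesothelial genes without V53188 (-0.93, 0.0354) and neutrophil genes without N53178 (-1.65, 0.0486). Interferon genes passed on the higher side without N53180 (0.34, 5.34e-04) or N53193 (0.27, 0.0195), blood endothelial genes without N53193 (0.34, 0.0373) or V53185 (1.02, 0.0363), and lymphocyte genes without N53193 (0.78, 0.0373).

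**Figure D5:**
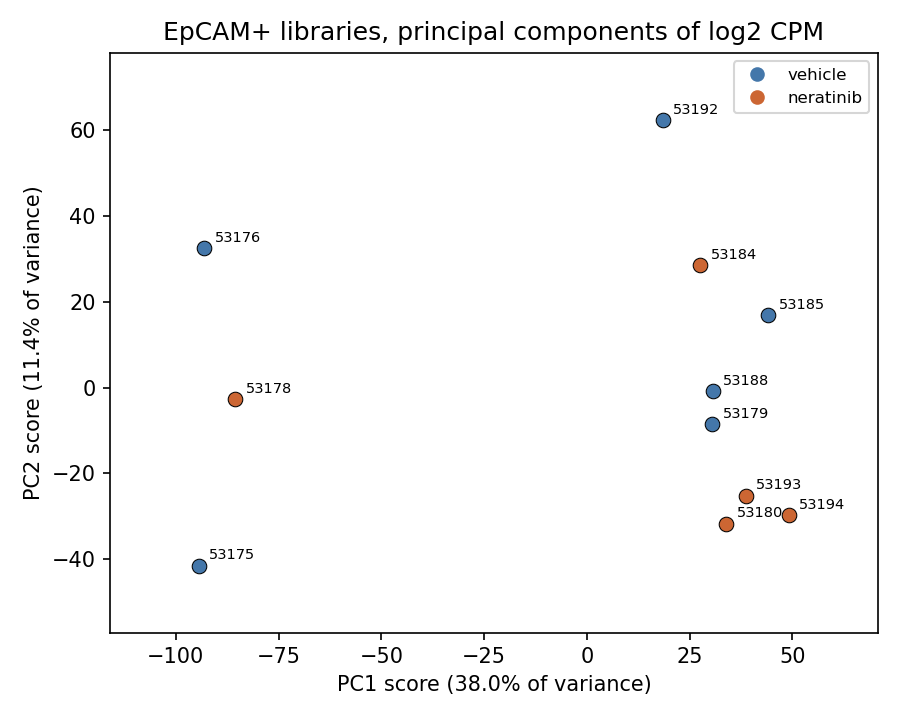
First and second principal component scores of the 11 EpCAM+ libraries, labelled by mouse and coloured by treatment. The libraries of mice V53175, V53176 (vehicle) and N53178 (neratinib) lie apart from the other 8 on the first component, which holds 38.04% of the variance.

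To examine whether the response to neratinib differed between the populations, the interaction was tested over all 19 libraries. With edgeR 13 of 19626 genes passed, 12 with a lower and 1 with a higher response in PDPN+ than in EpCAM+ cells. An unadjusted p under 0.05 was reached by 2190 genes, where chance gives 981.3. The fit shares 1 dispersion per gene between PDPN+ libraries and EpCAM+ libraries, whose spread was smaller. The SEs of PDPN+ responses, and so the calls that rest on them, may therefore be too small and too many. The 13 genes were mostly genes with reads in PDPN+ vehicle libraries and close to none in PDPN+ neratinib libraries. Trmt61b (ENSMUSG00000085492), a transfer RNA methyltransferase gene, had 2.09 to 14.6 CPM in the 4 PDPN+ vehicle libraries and 0 reads in the 4 PDPN+ neratinib libraries, and so was at least 66.7-fold lower against a floor of 3 reads in the shallowest library, with 7.45 ± 1.44 and 6.72 ± 1.21 CPM in EpCAM+ vehicle and neratinib libraries (adjusted p = 8.81e-04). Plekhb1 had 9.65 to 36.5 CPM against 0 to 0.147 (log2 difference of responses -8.89, adjusted p = 0.00352), D3Ertd751e 2.42 to 23.6 against 0 to 0.108 (-8.75, 0.00265), and Nudt12, a hydrolase gene, 0 to 37.0 against 0 to 0.0366 (-10.31, 0.0275), with all 4 neratinib libraries below the vehicle mean in each. Large2, a glycosyltransferase gene, went the other way, with 0 to 0.133 CPM against 3.40 to 14.0 in all 4 neratinib libraries (7.24, 0.00352). In EpCAM+ cells the means of Large2 were 18.5 ± 3.46 and 21.4 ± 5.02 CPM.

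With mouse as a block over the 8 mice with both populations, edgeR called 0 genes for the interaction (347 at an unadjusted p under 0.05), and the same 16 libraries without the block gave 1, Trmt61b. DESeq2 called 671 genes and limma voom 4, and leaving out mouse V53175, V53188, N53194, N53178, N53180 or N53184 gave 50, 48, 33, 20, 8 and 8 genes. Without 2 PDPN+ (V53175, V53188) and 3 EpCAM+ libraries (V53175, V53176, N53178) that stand apart, edgeR called 314 genes, 12 higher and 302 lower. That fit was chosen after the data were seen. The call of Nudt12 ended without each of 9 mice, at adjusted p of 0.0940 (N53178), 0.172 (N53180), 0.128 (N53184), 0.0731 (N53194), 0.0698 (V53179), 0.0506 (V53185), 0.0526 (N53193), 0.0539 (V53176) and 0.0618 (V53192).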

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

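The tests chosen only after the result was seen were the splits for the gene counts of the 2 neratinib comparisons, the comparison of treatments for the 3 EpCAM+ libraries, both tests of the acinar genes, and every value that uses GC offsets, length offsets with mouse as a block, the 16 libraries of the mice with both populations without a block, unmatched transcripts, or libraries that stand apart.

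Other splits of the same libraries put the neratinib results in proportion. For the gene counts of 0 by edgeR every split reaches the real count by construction, 35 of 35 in PDPN+ cells (highest other 0; 331 at an unadjusted p under 0.05, 73 by DESeq2) and 100 of 100 in EpCAM+ cells (highest other 430; 524 and 15), so these splits decide nothing. In PDPN+ cells 20 of 35 splits gave as many lists as the real 3 (highest other 12). In EpCAM+ cells 42 of 100 gave as many lists as the real 9 (highest other 17). For the interaction 43 of 100 gave as many genes as the real 13. The other splits gave 1732 to 3650 genes at an unadjusted p under 0.05, against the real 2190 and 981.3 by chance. Small p-values of the interaction were thus more frequent than chance gives under every split, so their excess is no sign of neratinib. Chance therefore cannot be excluded for the 2 list counts and the interaction. The interaction splits kept the libraries that stand apart. Without these libraries the real count was 314, and no splits were run for that fit. What gave 1 split 868 genes for the interaction, against the real 13, was not tested. Only the difference between populations stood out, with 1 of 100 splits, the real one, reaching 9673 genes (highest other 2936). Swapping the populations within mice gave 6639 at most besides the real split.

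The first pattern weighed is the 3 EpCAM+ libraries V53175, V53176 and N53178, which lie apart from the other 8 on the first principal component. Their GC and length trends differ from those of the other 8, but after a GC trend per library was removed the component still held 36.59% of the variance, from 38.04%, and after a length trend 36.60%, which argues against either trend as the whole cause. Islet cells as the whole cause are argued against by 68 abundant genes over 4 times lower in each of the 3 than in every other library. Without islet marker genes the component still held 38%. The mean log2 CPM of islet genes was nonetheless highest in these 3 libraries, at 5.33 to 5.78, against 0.20 to 4.29 in the other 8. Neratinib is argued against by 1 of the 3 libraries coming from the smaller treatment group and 2 from the other. With both trends removed together the component held 34.61%. The 3 libraries also carry the lowest animal numbers among the EpCAM+ libraries. Whether handling followed that order was not tested, nor were other differences in handling or in the tumours. Epcam in N53178, which is among the 3, stood at 622.8 CPM against 195.9 in the nearest neratinib library. Whether Epcam follows this pattern was not tested.

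The second pattern is the lower acinar genes in EpCAM+ cells with neratinib. RNA or cells from acinar tissue in some libraries is a candidate explanation, and the EpCAM+ sort is the gate that would remove cells without EpCAM. Whether acinar cells carry EpCAM, and so would pass that gate, was not tested. Most of the 13 genes go up and down together over the 11 libraries, with a median pairwise Spearman correlation of 0.790 (0.7899) over 78 pairs (lowest -0.147). They could do so under a neratinib effect as well, so the correlation does not tell the 2 explanations apart. An effect of neratinib stays open, with an exact permutation p of 0.0671 for the mean log2 CPM of the list (1.09 ± 3.48 with vehicle, n = 6, and -2.44 ± 1.10 with neratinib, n = 5). The acinar mean of N53184 was far from the rest of its group in both populations, at -0.49 (-0.493) in PDPN+ and -0.49 (-0.4897) in EpCAM+ cells. Among the 8 mice with both populations, N53184, V53185 and V53188 had the highest acinar means in each population. Those of V53185 and V53188 were -1.135 and -1.394 in PDPN+ and 3.558 and 2.672 in EpCAM+ cells. Acinar RNA thus went with the mouse in both sorts, at low levels in PDPN+ cells. This was not tested and does not exclude an effect of neratinib.

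The third pattern is the genes with reads in PDPN+ vehicle and almost none in PDPN+ neratinib libraries, which carry the interaction, and 2 of the 4 vehicle libraries, V53175 and V53188, stand apart from the other 6 PDPN+ libraries. The response differed between the populations for 13 genes, with log2 differences of -8.75 for D3Ertd751e, 7.24 for Large2, -10.31 for Nudt12, -8.89 for Plekhb1 and -11.27 for Trmt61b. Transcripts missed at random in small PDPN+ samples stay possible, but splits of the 8 libraries do not decide it. Of 35 splits, 12 gave as many genes on in 4 libraries and off in the other 4 as the real 4 (highest other 31). The splits with 31 and 30 genes had V53175 and V53188, the libraries with the fewest genes, on the off side. In the real split both are vehicle libraries, and 3 of the 4 genes were on with vehicle and off with neratinib. For neratinib, 0 of the 13 genes passed both with sample weights and with mouse as a block. The reading written before that count was known would have set fewer than 4 of 13 against neratinib. It was replaced after the count was known, because the fit with mouse as a block has fewer libraries and a call lost that way excludes nothing: the same 16 libraries without the block called 1 gene, and the log2 difference of Trmt61b was -10.93 with the block against -11.27. Under the original reading the count of 0 would argue against neratinib, and under the replaced one the question stays open.

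A transcript without a gene match, ENSMUST00000241538.1, had 0 reads in the 6 EpCAM+ vehicle libraries and 1.73 ± 0.684 CPM in the 5 neratinib libraries (lowest 1.07), at least 26.3-fold higher against a floor of 3 reads in the shallowest library. Its fitted log2 fold change was 9.51 (9.515; edgeR adjusted p = 0.0394, higher in 5 of 5). The gene comparisons leave such transcripts out, and with them as features the interaction had 15 features past the threshold, 14 lower and 1 higher, including all 13 genes.

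Single libraries lay far from their group in 13 of 136 sets of values, where chance gives 6.8. The share of haemoglobin reads was 0.00180% in PDPN+ N53180, 0.00367% in PDPN+ V53185, 7.59e-04% (0.0007588) in EpCAM+ N53180 and 0.00541% in EpCAM+ V53176. Dusp6 stood at 257.7 CPM in PDPN+ N53180 and Etv5 at 4.28 in PDPN+ V53179. Mean log2 CPM was 3.95 for mesothelial genes in PDPN+ V53188, 0.72 for red cell and platelet genes in EpCAM+ N53180, 9.18 for dissociation stress genes in EpCAM+ V53175 and -1.53 for lymphatic endothelial genes in EpCAM+ V53185.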

How the results depend on the processing

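Of the settings in this part, the tests chosen only after the data were seen were GC offsets, length offsets with mouse as a block, unmatched transcripts as features, and the fits that mark or leave out libraries that stand apart or the 3 mice with EpCAM+ cells alone; the other settings in this part were chosen before the data were examined. The population count stayed within 1.5 times of 9673 under every alternative (6792 to 12346; leaving out each mouse 9092 to 10099), of which the fit with mouse as a block (paired) gave 6792; the block was fitted for the populations and the interaction alone. Block and voom moved the median of all genes by -0.41 and -0.26, and in PDPN+ cells voom moved it by -0.15. PDPN+ gene counts of 0 by edgeR (331 at an unadjusted p under 0.05) became 73 with DESeq2 and 111 with all 19 libraries in 1 fit, and were 0 under the other alternatives; EpCAM+ counts of 0 (524) became 15 with DESeq2 and 1 with unmatched transcripts as features. The interaction count of 13 became 671 with DESeq2 (12 shared), 4 with voom, 0 with mouse as a block, 0 with GC or length offsets and the block, 1 with the 16 libraries and no block, and 314 without 2 PDPN+ (V53175, V53188) and 3 EpCAM+ libraries (all 13 shared). Leaving out each mouse gave 8 to 50 (V53175 50, V53188 48, N53194 33, N53178 20, N53180 8, N53184 8). PDPN+ lists, 3 of 33, became 0 with an estimated correlation, with fry, with GC offsets and an estimated correlation, and without 2 vehicle libraries with an estimated correlation; leaving out each library gave 1 (N53178) to 5 (V53188). EpCAM+ lists, 9 of 34, became 0 in the same 3 settings and, with an estimated correlation, when the 3 libraries were marked or left out; leaving out each library gave 4 (N53178, V53192) to 14 (V53175), with 5 without V53179. No named gene past the threshold and no passing list test changed direction, but the median of the macrophage list in EpCAM+ cells went from 0.38 to -0.12 without N53178, where its call ended, and that of the fibroblast list from 0.17 to -0.78 without N53194, where it passed. The cause of these changes was not tested, except that the block uses fewer libraries. Of the called list values over all alternatives, 30 of 45 (PDPN+) and 108 of 180 (EpCAM+) stayed past the threshold. The median SE of a log2 fold change was 1.06 in PDPN+ and 0.28 in EpCAM+ cells. Depth was not varied; it limits a count of 0 to at most 0.110 CPM at 3 reads in the shallowest library.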

Other observations

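Xist, expressed from the inactive X chromosome, stood at 109 to 237 CPM in the 8 PDPN+ libraries and 289 to 710 in the 11 EpCAM+ libraries. Of the Y-linked genes, Ddx3y and Eif2s3y each had reads in 1 of 8 PDPN+ and 1 of 11 EpCAM+ libraries, Uty in 5 of 8 and 2 of 11, and Kdm5d in 8 of 8 and 11 of 11, with at most 0.271 and 0.272 CPM for Kdm5d. These genes and those below were chosen after their values were seen. Mesothelial genes were abundant in PDPN+ libraries, with Wt1 at 84.9 to 224 CPM, Upk3b at 299 to 1034 and Msln at 170 to 1113, while Msln was also at 751 to 1287 in EpCAM+ libraries. Islet hormone genes were present in EpCAM+ libraries, with Ins2 at 9.24 to 932 CPM and Gcg at 1.99 to 253. No test of their origin was run.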
